A study of Mus musculus with 6 samples.

How the data were processed

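RNA-seq of hippocampal microglia from mice at 3 weeks after birth was analysed in 6 libraries, 3 Ctrl and 3 FGR, grouped by the titles in the labels. Per the labels' protocols, RNA of 3000 microglia was made into libraries with the SMARTer Stranded Total RNA-Seq Kit v2, a random-primed total RNA kit. The authors deposited 1 table of whole-number counts of reads per gene ID, not normalized, with 54590 Ensembl IDs and 1 column per library. Per the submitters' processing notes, the tools were Trim Galore 0.6.5, Bowtie2 2.4.5, SAMtools 1.3.1, HTSeq 2.0.3 and DESeq2 1.32.0, and the genome build was mm10. The role of each tool, the annotation, the strand setting of the counting and the way microglia were isolated are not given in the sources used here. How growth was restricted is not given either. Bowtie2 does not split reads across introns, which lowers the counts of transcripts with short exons. Reads of mitochondrial copies in the nuclear genome and of overlapping genes such as mt-Atp6 and mt-Atp8 can be shared or lost in counting.

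Symbols were taken from a table of gene names, which matched 53620 of the IDs; the 970 others held 0.145% of the counts. Positions are those of the GENCODE M21 annotation on GRCm38 and were not converted. Every column of the table was mapped to a sample. All totals, CPM values and tests were computed here from the deposited counts with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Totals of 1553588 to 11364316 counts per library set the precision, and counts made of both mates of a pair are not independent molecules.

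The main comparison, FGR against Ctrl over all 6 libraries, used edgeR's quasi-likelihood test with TMM scaling, its filterByExpr filter, robust dispersion and quasi-likelihood fits and bias-adjusted deviances. A feature was called at a Benjamini-Hochberg adjusted p under 0.05, and the SE is the log2 fold change divided by the square root of F. Of the 54590 IDs, 16075 passed the filter. Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, separately for 25 microglial lists and 13 lists of other cell types and sex-linked genes. The lists held 1138 entries, 3 of them without an ID in the table. Library measures were compared with exact two-sided permutation tests of 3 against 3, which cannot give a p under 0.1. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule, where fewer than 5 features passed in a direction, the 8 with the smallest p, a mean of at least 5 CPM and a symbol that is not a clone or prediction name were given; of each list described, up to 4 members with the smallest p were given; and Tmem119, P2ry12, Cx3cr1, Apoe, Xist and Ddx3y were always given, with a further gene of the rule not reported here.

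Before averaging, libraries were compared in pairs by the chi-square of their counts over features. Libraries 1 and 2 of each group were close to sampling noise and were counted as 1 sample in each mean, SD and n. The edgeR fit kept all 6 libraries as fixed beforehand, and the fit on summed pairs was added after seeing the data. In data simulated with libraries 1 and 2 sharing their biological draw (coefficient of variation 0.391), 13.5% of unchanged features had p under 0.05 in the 6-library fit, which recovered 6 of 100 features changed 2-fold and 30 of 100 changed 4-fold with 15 false calls; the fit on summed pairs gave 4.5% and no false call. This simulation had no difference between the sets of libraries, which the data do have. Its coefficient of variation came from the fit on summed pairs without the replicate block, where the difference between sets counts as noise. The common coefficient of variation was 0.383 in that fit and 0.206 with the block, so the recovery says nothing of a fit with the block. In the data the 6-library fit gave 602 features at p under 0.05, fewer than the 804 expected, so it was not settled whether its p-values are too small.

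The replicate numbers recur in both groups, and it was checked whether they pair the libraries. Deviations from the group mean had correlations of 0.21, 0.169 and 0.477 between libraries of number 1, 2 and 3. Library 1 of a group deviated with library 2 of the other group to a like degree (0.205 and 0.194), so what the numbers share is the set, libraries 1 and 2 or library 3. The pairing comes from these values and not from a label, and the fit with the replicate block is given where it changes a count. Alternatives covered other scalings, filters, thresholds and tests, features left out, each library left out in turn, the replicate block, DESeq2 and limma-voom.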

Results

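Total RNA from microglia, the resident macrophages of the brain, was sequenced from the hippocampus of mice at 3 weeks after birth. The mice carried 1 copy of a Tmem119-tdTomato reporter, a red fluorescent protein under the microglial gene Tmem119. There were 3 libraries from control mice (Ctrl) and 3 from mice labelled FGR, which the series title ties to restricted growth in the womb. Each library was made from the RNA of 3000 microglia. The comparison asks how restricted growth before birth bears on the microglial transcriptome. Counts in Ctrl libraries 1, 2 and 3 summed to 2972721, 1553588 and 10201412, and those in FGR libraries 1, 2 and 3 to 3358142, 1783494 and 11364316. Between 29930 and 41143 of the 54590 features had a count above 0 in a library. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

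Mitochondrially encoded RNA was abundant under its own labels, while C1qa, Tmem119, Apoe, Cx3cr1, Actb, Rpl3 and Malat1 had few counts under theirs. The mitochondrial 16S ribosomal RNA mt-Rnr2 held 9.99% of the 31233673 counts of all 6 libraries, and the 12S ribosomal RNA mt-Rnr1 held 4.75%. The feature labelled C1qa, a complement subunit that microglia make in large amounts, had 3 counts over all 6 libraries. Those labelled Tmem119 (29 counts), Apoe (22) and the fractalkine receptor Cx3cr1 (47) also had few counts, while the purinergic receptor P2ry12 had 873. Cytoskeletal actin Actb and ribosomal protein Rpl3, which every cell uses, had 44 counts each. Malat1, an abundant nuclear RNA of nearly all cells, had 276 counts. As whole lists, nuclear labels were not uniformly low. Against 10000 random lists of protein-coding IDs of like length, the median count per kb of the homeostatic microglia list lay at percentile 96.2 (64.8 counts per kb, 30 members) and that of the nuclear oxidative phosphorylation list at 99.99 (57.6, 75 members). The cytosolic ribosomal protein list lay at percentile 87.7, the lysosome list at 78.8, the complement and engulfment list at 35.9 and the neuron list at 28.5. The 13 mitochondrially encoded mRNAs had a median of 44299 counts per kb. The feature labelled Frmd8 had 1375516 counts, 4.4% of the total and the third most of any feature. On the minus strand of chromosome 19 of GRCm38 (mm10), the annotation places Malat1 at 5795690 to 5802672 and Frmd8 at 5849702 to 5875274. Nuclear features are named below by the label in the count table, with no statement of what the gene does.

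**Figure D1:**
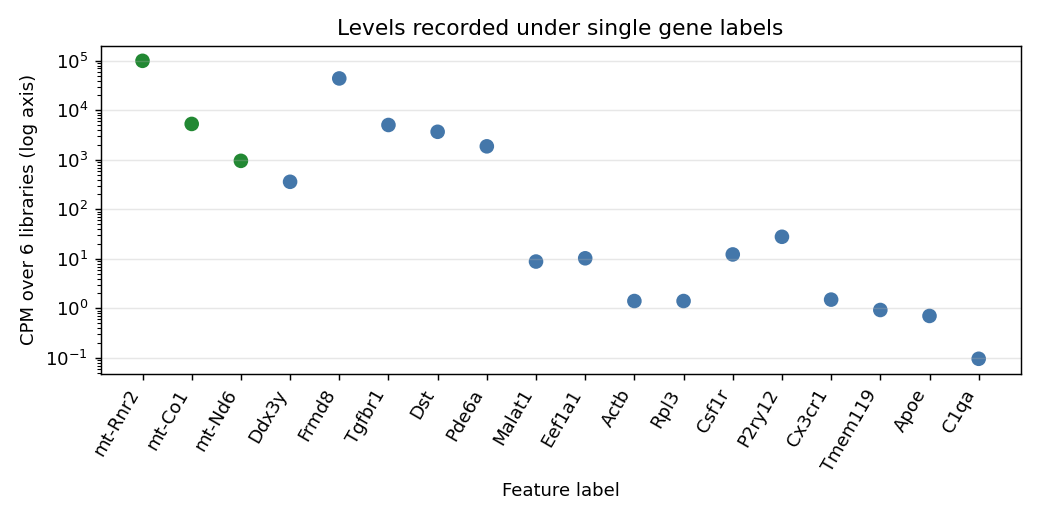
CPM over all 6 libraries together (log axis) for single feature labels; green points are mitochondrially encoded and blue points are nuclear. Frmd8, with 1375516 counts, stands near mt-Rnr2, while C1qa, with 3 counts, is the lowest point.

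Libraries 1 and 2 of each group were near copies of each other, and each pair was counted as 1 sample, so n = 2 per group in every mean ± SD. Fold changes and SEs are instead from the fit on 6 libraries unless another fit is named. That fit counts the near copies as separate, and the SE of each feature given with one was larger with the pairs summed. Among features with 1000 to 9999 counts in a pair of libraries, the chi-square of the counts was 2.63 per feature between Ctrl 1 and 2 and 2.77 between FGR 1 and 2. Among features with 20 to 99 counts it was 2.35 and 2.37, so the excess over counting noise was nearly a constant factor, and beyond it libraries 1 and 2 differed by little more than the sampling noise. The other 13 pairs of libraries gave 20.4 to 51.7 in the higher range. Even counts were in excess in every library: among features with low counts, from 2 upwards, 61.9% to 67.9% had an even count. The first principal component, with 41.5% of the variance, set library 3 of both groups apart from libraries 1 and 2.

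**Figure D2:**
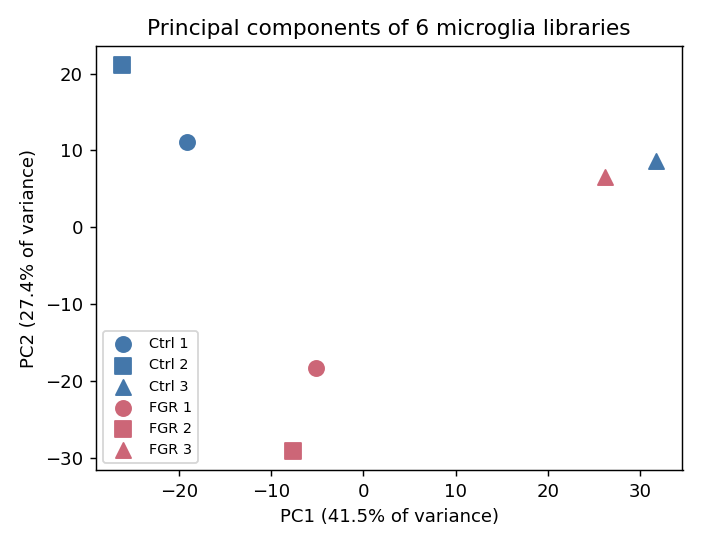
First and second principal components of log2 CPM for the 6 libraries; blue is Ctrl, red is FGR, and the marker shape gives the library number. Library 3 of both groups lies to the right on the first component, which carries 41.5% of the variance, and libraries 1 and 2 of each group lie close together.

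Between FGR and Ctrl microglia, the mitochondrial ribosomal RNAs took 15.5% ± 0.716 of the counts in FGR and 13.7% ± 0.185 in Ctrl (SD, n = 2). All 3 FGR libraries lay above all 3 Ctrl libraries, at 14.6%, 15.3% and 16.0% against 13.4%, 13.8% and 13.8%. The exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest it can give, and the adjusted p over 18 library measures was 0.36. This test counts the near copies as separate, and an exact test of 2 against 2 samples can give no p under 0.333. The 16S ribosomal RNA mt-Rnr2 (chromosome M, 1094 to 2675) stood at 111887 ± 1305 TMM-scaled CPM in FGR and 93706 ± 4253 in Ctrl, a log2 fold change of 0.28 (SE 0.11) with an edgeR adjusted p of 0.9965. With the near copies summed, the log2 fold change of mt-Rnr2 was 0.284 (SE 0.275). For mt-Rnr1 (chromosome M, 70 to 1024) the log2 fold change over all libraries was 0.13 (SE 0.13), which became 0.02 without FGR library 3 and 0.23 without FGR library 1. Mitochondrially encoded mRNA as a whole took 2.43% ± 0.222 of the counts in FGR and 2.27% ± 0.346 in Ctrl. The exact two-sided permutation test of 3 against 3, which ignores the library numbers, gave p = 0.6 (adjusted p 0.7875). Within each number FGR lay above Ctrl, at 2.54% against 2.48%, 2.63% against 2.55% and 2.27% against 2.03%, where the first 2 of these come from near copies and count as 1 pair.

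Of the 13 mitochondrially encoded mRNAs, 10 had a fold change above 1 and 3 below 1 in the 6-library fit, and none passed the test over all features. With the near copies summed, the log2 fold changes of mt-Nd3 and mt-Co2 moved from -0.04 and -0.05 to 0.07 and 0.09. mt-Atp6 (chromosome M, 7927 to 8607), a subunit of the ATP synthase, stood at 1694 ± 311 CPM in FGR and 1228 ± 233 in Ctrl, with a log2 fold change of 0.59 (SE 0.17). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave it an adjusted p of 0.9965 over all features and 0.0466 adjusted over the list alone, where it was the 1 call. That call was lost with each pair of near copies summed, where the log2 fold change was 0.47 (SE 0.30) and the edgeR adjusted p over the list alone 0.8121. It was also lost without Ctrl library 1 (0.3285), Ctrl library 2 (0.2873), FGR library 1 (0.2416) or FGR library 2 (0.3978), and with library totals (0.0884), upper quartile scaling (0.0795), limma-voom (0.0766), the non-robust fit (0.0609) or a filter of 1 (0.0758) or 10 CPM (0.0798) in 3 libraries. In library 3, mt-Atp6 stood at 1474 CPM in FGR and 1393 in Ctrl. The cytochrome oxidase subunit mt-Co1 had a log2 fold change of 0.22 (SE 0.15), the complex I subunit mt-Nd5 had 0.17 (SE 0.13), and mt-Atp8, which overlaps mt-Atp6, had -0.36 (SE 0.24). With the near copies summed, these were 0.25 (SE 0.28), 0.21 (SE 0.27) and -0.19 (SE 0.32). Scaling and filter moved them too. With library totals mt-Co1 was 0.13, mt-Nd5 0.08 and mt-Atp8 -0.44. With no filter on low counts they were 0.32, 0.26 and -0.26. Leaving out 1 library moved mt-Atp8 to -0.16 (without FGR library 2) or -0.72 (without FGR library 3), and mt-Co1 to 0.34 (without FGR library 3). As a list, the mitochondrially encoded mRNAs gave an adjusted p of 0.6707 by camera, and 0.8543 as adjusted p with an estimated correlation. The camera adjusted p was 0.1831 with the near copies summed, and 0.0338, past the threshold, with no filter on low counts.

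**Figure D3:**
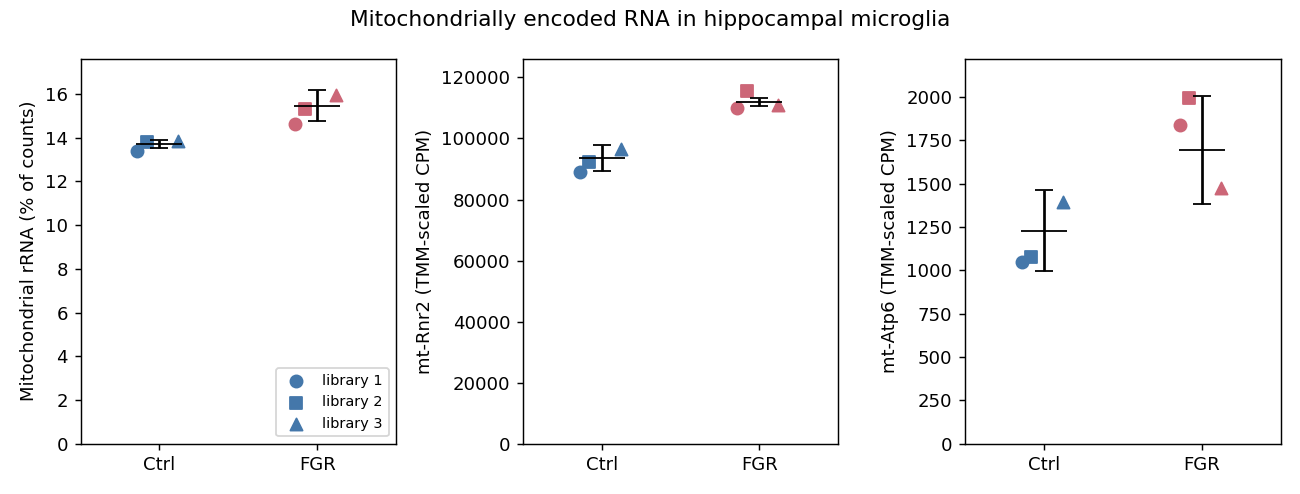
Share of counts in the mitochondrial ribosomal RNAs (left, percent) and TMM-scaled CPM of mt-Rnr2 (middle) and mt-Atp6 (right) in Ctrl (blue) and FGR (red) libraries, with marker shapes for library numbers. Bars give the mean ± SD of 2 samples per group, libraries 1 and 2 averaged as 1; mt-Rnr2 averages 93706 CPM in Ctrl and 111887 in FGR.

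Over the whole transcriptome, no feature passed the test between FGR and Ctrl microglia: 0 of 16075 tested features passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 0 higher and 0 lower. At an unadjusted p under 0.05 there were 602 features, against 804 expected by chance; with the replicate block, 1360 of the same features were. limma-voom also called 0 features and DESeq2 called 1, labelled Gm36947, with 116 counts in all. With the replicate block, edgeR called 1 feature, labelled Nprl3, higher in FGR (adjusted p = 0.0249, log2 fold change 1.43); its CPM was 118.7 in FGR library 3 and 40.5 in Ctrl library 3, and 9.77 and 4.91 in the means of libraries 1 and 2. With the near copies summed and the replicate block, Nprl3 was not called and Gm36947 was. Both features are named here after their values were seen. With the near copies summed to 2 samples per group, edgeR called 0 of 24149 features, with 327 at an unadjusted p under 0.05 against 1207 expected, and 1049 when the replicate block was added. Leaving out Ctrl library 3 gave 273 calls, 83 higher and 190 lower, but Ctrl was then only a pair of near copies, 1 sample with technical spread, so these calls were not read as differences between groups. Their median absolute log2 fold change was 2.1, against 0.14 in the called direction between the third libraries of the groups, where 167 had the same sign. In simulated data with this number of samples and libraries 1 and 2 sharing their biological draw, but no difference between the sets of libraries, edgeR on summed pairs recovered 0 of 100 features changed 2-fold and 14 of 100 changed 4-fold. The simulated variation was that of the fit without the block, in which the sets count as noise, so this does not bear on the fit with the block.

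The features with the smallest p values are given with their values, since none passed the test. Of those higher in FGR, the feature labelled Ctsq stood at 11.6 ± 0.52 CPM in FGR and 4.3 ± 0.39 in Ctrl, and Olfr312 at 34.0 ± 7.56 and 17.0 ± 3.74. Their log2 fold changes were 1.49 (SE 0.36) and 1.05 (SE 0.28), with SEs of 0.464 and 0.363 with the near copies summed. Besides mt-Atp6, the others were Olfr918 at 1.33, St6galnac1 at 0.76, Tspan18 at 0.68, Trpt1 at 0.68 and Kansl3 at 0.57 on the log2 scale. Of those lower in FGR, Skap2 stood at 107.7 ± 5.39 CPM in FGR and 163.3 ± 30.4 in Ctrl, and Cadps at 43.7 ± 10.3 and 71.9 ± 10.8. Their log2 fold changes were -0.64 (SE 0.18) and -0.77 (SE 0.21), with SEs of 0.286 and 0.312 with the near copies summed. The remaining log2 fold changes were -1.47 for Dnah7b, -1.40 for Usp47, -1.37 for Napb, -1.36 for Huwe1, -0.98 for St8sia4 and -0.83 for Tbck. All 16 had an edgeR adjusted p of 0.9965.

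None of the 25 lists of genes fixed for microglial states and pathways passed an adjusted p of 0.05 between FGR and Ctrl by camera, and no member of any list passed over all features. Each list was read as a set of labels, since several genes known to be abundant had few counts under theirs. In the fit on all libraries, which counts the near copies as separate, the glycolysis list came nearest. It had 13 of 16 tested features above 1 in fold, a median log2 fold change of 0.29 and an adjusted p of 0.1326. That adjusted p was 0.8543 with an estimated correlation. Its members of smallest p were Hk2 at a log2 fold change of 0.43, Aldoa at 0.32, Pgk1 at 0.55 and Pfkl at 0.31. With each library left out in turn, Pgk1 ranged from 0.34 (without FGR library 1) to 0.92 (without FGR library 3). The highest values of Pfkl (0.52) and Aldoa (0.48) were without Ctrl library 3. The antigen presentation list had 14 of 18 features above 1, a median log2 fold change of 0.25 and an adjusted p of 0.4117, which was 0.8543 with an estimated correlation. Its members of smallest p were Psmb8 at 0.64, H2-Aa at 1.04, H2-Ab1 at 0.88 and Nlrc5 at -1.14. H2-Aa was 0.44 without FGR library 3, H2-Ab1 was 0.34 without Ctrl library 3 and 0.52 without FGR library 3, and Nlrc5 kept its sign at -1.66 to -0.90 with each library left out. With the near copies summed no list passed, and antigen presentation came nearest, at a camera adjusted p of 0.0731. The mitochondrially encoded and the nuclear oxidative phosphorylation lists then had 0.1831 each, and glycolysis had 0.2551. With no filter on low counts, or one of 1 CPM in 3 libraries, the antigen presentation and glycolysis lists passed. Both settings let in more features of low count. With a filter of 10 CPM in 3 libraries neither list passed. The antigen presentation list also passed with the near copies summed and the replicate block, and glycolysis passed without FGR library 3, which left only near copies in FGR. Of the always-reported identity genes, P2ry12 stood at 24.9 ± 1.98 CPM in FGR and 33.2 ± 1.4 in Ctrl, a log2 fold change of -0.37 (SE 0.26). It ranged from -0.57 without Ctrl library 1 to -0.21 without Ctrl library 3, and its CPM in Ctrl libraries 1, 2 and 3 was 21.9, 42.5 and 34.2. The labels Tmem119, Cx3cr1 and Apoe were under the filter on low counts and were not tested.

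Of 12 tested lists of labels for other cell types and sex-linked genes, 0 passed an adjusted p of 0.05 by camera, with a lowest adjusted p of 0.2739. In these libraries the summed CPM of the neuron list was 1537 ± 96.4 in FGR and 1557 ± 150 in Ctrl, and that of the oligodendrocyte list 660 ± 36.1 and 635 ± 3.12. The summed CPM of the border-associated macrophage list was 263 ± 0.651 in FGR and 291 ± 2.37 in Ctrl, of the monocyte and dendritic cell list 243 ± 12.5 and 278 ± 7.79, and of the lymphocyte list 309 ± 18.2 and 355 ± 2.16. For each of these 3 lists all 3 FGR libraries lay below all 3 Ctrl libraries on this scale. The exact two-sided permutation test of 3 against 3 gave p = 0.1, with an adjusted p of 0.36 over the 18 measures. These sums are CPM of library totals, while the CPM of single features compared between groups are TMM-scaled. The TMM factors were lower in FGR (0.964 to 0.973) than in Ctrl (0.995 to 1.059), which raises FGR values against Ctrl. The separation may thus depend on the scaling, which was not tested. The 50 most abundant features took 29.6% ± 0.694 of the counts in FGR and 28.0% ± 0.192 in Ctrl, with all 3 FGR libraries above all 3 Ctrl libraries and the same exact p of 0.1. They include both mitochondrial ribosomal RNAs, and without these the share was 14.1% ± 0.022 in FGR and 14.3% ± 0.007 in Ctrl.

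The 4 Y-linked labels Ddx3y, Eif2s3y, Kdm5d and Uty were detected in all 6 libraries, at 99.6 to 549.5 CPM, and did not separate FGR from Ctrl. Ddx3y stood at 418 ± 56.9 CPM in FGR and 390 ± 173 in Ctrl, a log2 fold change of 0.01 (SE 0.23). Uty had a log2 fold change of -0.15 (SE 0.16), Eif2s3y -0.15 (SE 0.19) and Kdm5d 0.04 (SE 0.18). The signs for Ddx3y and Kdm5d turned negative with library totals, upper quartile scaling or a filter of 10 CPM in 3 libraries, and both signs occurred with each library left out. Eif2s3y then ranged from -0.28 (without Ctrl library 3) to -0.05 (without Ctrl library 1), and Uty was -0.07 without FGR library 1. The feature labelled Xist stood at 3.02 ± 0.87 CPM in FGR and 7.29 ± 3.77 in Ctrl, a log2 fold change of -1.29 (SE 0.51) with an edgeR adjusted p of 0.9965.

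The FGR-to-Ctrl ratios seen in libraries 1 and 2 were not correlated with those in library 3. Across 9392 features with a mean of at least 10 CPM, the correlation of the log2 ratios between both sets of libraries was -0.01, and 50.9% of features had the same sign. This is a correlation across features, which are not independent replicates. The difference between the sets of libraries carried 59% of the variance among the 4 samples, the group 20.2% and their interaction 20.7%. No label names a batch. Library 3 had 10201412 counts in Ctrl and 11364316 in FGR, against 1553588 to 3358142 in libraries 1 and 2 of both groups. The difference between the sets thus cannot be told apart from one of sequencing depth.

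**Figure D4:**
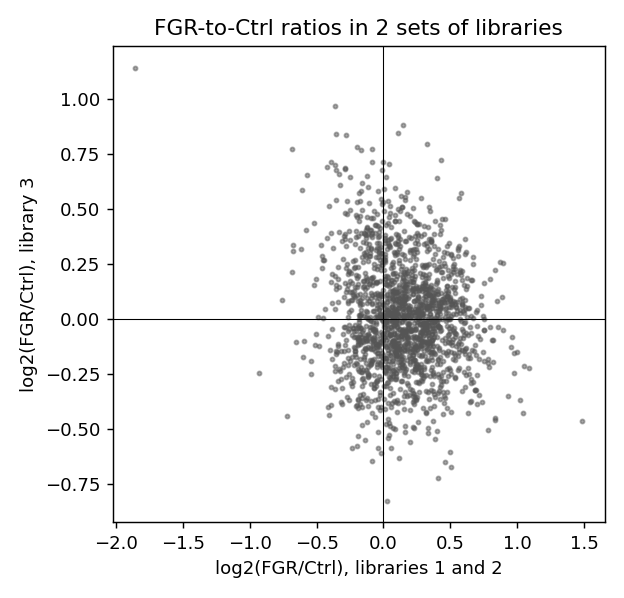
Log2 ratio of FGR to Ctrl in libraries 1 and 2 (horizontal) and in library 3 (vertical), each point 1 of 1758 features with a mean of at least 100 CPM, computed on CPM plus 2. The points form no rising diagonal (r = -0.153 across these features).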

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

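The summing or averaging of libraries 1 and 2, alone, with the replicate block or with DESeq2, and the filter of 10 CPM in 3 libraries, were chosen after seeing the data. The count of 0 features was unchanged under the other scalings, the filters of 1 and 10 CPM in 3 libraries (26908 and 9467 features tested, against 16075), limma-voom, the legacy and the non-robust edgeR fits, the other thresholds, removal of the mitochondrial, ribosomal RNA and most abundant features or of the sex-linked genes, and the near copies summed by edgeR or DESeq2. It was 1 (lower) without a filter on low counts and 1 (lower) with DESeq2, in both cases Gm36947. It was 1 (higher) with the replicate block, and 1 (lower, Gm36947) with the near copies summed and the replicate block. With each library left out in turn, the counts were 0 to 273 in all, 0 to 83 higher and 0 to 190 lower, the highest values all without Ctrl library 3, where Ctrl is only near copies, 1 sample with technical spread.

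The count of 0 microglial lists was 3 without a filter (antigen presentation, glycolysis and mitochondrially encoded genes), 2 with the filter of 1 CPM, which also let in more features, 0 with that of 10 CPM, and 1 with the near copies summed and the replicate block; the cause was not tested. It was 0 to 1 with each library left out, the 1 without FGR library 3, where FGR is only near copies. The replicate block changed no other call. The 0 lists of other cell types and the 0 library measures at p under 0.05 did not move, but neither 3 against 3 nor 2 against 2 samples can pass that threshold in an exact test (smallest p 0.1 and 0.333).

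Signs turned only for values near 0. On the log2 scale Eif2s3y was 0.019 with DESeq2 on summed pairs, and mt-Nd3 and mt-Co2 were 0.074 and 0.093 with edgeR on summed pairs. With library totals Kdm5d was -0.048 and Ddx3y -0.082, and with upper quartile scaling they were -0.025 and -0.064, and with the 10 CPM filter -0.02 and -0.062. Leaving out each library gave -0.069 to 0.145 for Kdm5d and -0.195 to 0.229 for Ddx3y. The sex-linked list had a signed -log10 p of 0.19 without a filter. The other features given with a fold change, and the antigen presentation, glycolysis and mitochondrially encoded lists, kept their sign where tested. Nprl3, Gm36947, mt-Nd3, mt-Co2 and the lists of single other cell types were not followed across all settings.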

Other observations

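All tests below except the scan for a single shift per chromosome and the comparison of microglial with neuronal gene bodies were chosen after the result was seen. That comparison used the shifts of a window scan that was itself chosen afterwards. These paragraphs offer hypotheses found and tested on the same data.

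Several genes that microglia use heavily had almost no counts under their own IDs, while mitochondrial and Y-linked labels held plausible levels. Counting on the opposite strand is argued against by mitochondrial RNA: mt-Rnr2 had at least 86.8 times the counts of mt-Nd6, the mRNA of the other strand, in each library. For a single displacement per chromosome between the IDs and the reads, a rise on most autosomes was predicted and not seen. A shift raised the share of abundant list genes on high-count exons above 20 random sets on 5 of 19 autosomes. The scan rested on 4 to 36 list genes per autosome, and whether it would find a true single shift was not simulated. It thus does not decide on a single displacement. A displacement that changes along each chromosome, as IDs and alignments on different genome builds could give, is a candidate explanation: in 17 of 89 pairs of neighbouring 25 Mb windows the best shifts agreed within 20 kb, against at most 9 in 100 draws with values moved along the window and at most 9 in 100 draws with counts permuted among the features of a chromosome. Features inside the shifted bodies of microglial and housekeeping genes then had a median log2 count per kb 3.88 above those in neuronal bodies (81 and 15 features). These lay in the bodies of 60 and 7 genes, so the neuronal side rests on few genes. The mirrored shift gave -0.40, with 10 neuronal features. It is no like control, since the window shifts were picked on the same counts to place them inside gene bodies and the mirrored ones were not.

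This explanation has limits. It was reached after earlier versions of the scan that decided nothing. Simulated data with stepped shifts gave 75 agreeing pairs, against the 17 found. The simulated shifts changed between neighbouring windows by less than the 20 kb tolerance, so their agreement was built in. Larger steps were not simulated, so 75 against 17 does not decide on a displacement with such steps. A simulation with IDs and reads unrelated gave 12 agreeing pairs, of which 4 had shifts of at least 20 kb, as all 17 did in the data. Bodies on the opposite strand, a control that gave 3 agreeing pairs in the simulation with stepped shifts, gave 21 in the data, more than the 17. The agreement thus did not need matching strands. If reads were counted by strand, this weakens the 17 pairs as evidence of a displacement. The simulation drew its counts by strand, while the strand setting of the real counting is not given. Counting without regard to strand was not simulated, so for that case the control does not decide. The scan does not tell the strand of the reads either. Loss of cytoplasmic RNA may also lower these genes and stays open. Cells other than microglia may lower the microglial ones among them, which stays open too. By themselves such cells would not account for Actb and Rpl3, which every cell uses and which had 44 counts each. The median of the cytosolic ribosomal protein IDs lay at percentile 87.7 of random lists of like length, neither low nor beyond chance. The nuclear oxidative phosphorylation IDs lay at percentile 99.99 and the homeostatic microglia IDs at 96.2, against 28.5 for the neuron list. The lysosome IDs lay at 78.8 and the complement and engulfment IDs at 35.9. Over 100 CPM stood 3 of 75 oxidative phosphorylation IDs, 5 of 30 homeostatic IDs and 3 of 30 neuron IDs. The random lists were matched on length, and displaced reads that fall on neighbouring IDs could give such percentiles. These values thus do not decide on a displacement of every ID or on cells without microglial RNA. If the IDs hold their own reads, the oxidative phosphorylation and homeostatic percentiles go against a complete loss of these mRNAs. A partial loss stays open, since it would lower the random lists too. Nuclear Malat1 had 276 counts, but as a single gene taken from the pattern itself it does not decide on such a loss. No biological explanation was tested.

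Libraries 1 and 2 of each group may be 1 library or 1 RNA measured 2 times. Their coefficient of variation beyond noise was at most 0.15 of that against library 3 of the same group. The noise taken off was scaled by the low-count chi-square of these same pairs (2.36), which draws their value toward 0. The chi-square itself has no such step, and was 2.63 and 2.77 for these pairs and at least 20.4 for all others at 1000 to 9999 counts. No label states such a relation, and pooled animals shared by both libraries would give the same values.

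That no feature separated FGR from Ctrl could come from fold changes that differ between the sets of libraries, with a correlation of -0.01 across features. A correlation near 0 is also what no effect of growth restriction at all would give, so these values do not choose between them, and a biological difference stays open and untested. The 10 splits of the 6 libraries are too few for a share under 0.05, and with a real count of 0 every split gives as many by construction, so they say nothing here (real 0, highest other 146). The 4 splits with library 3 of both groups on one side gave 146, 91, 0 and 0 calls, so their calls do not follow from the sets alone. At an unadjusted p under 0.05 these 4 gave 1680 to 3117 features, and the 6 splits with library 3 on both sides 149 to 602, which points to the sets as a structure of these samples. Of the splits that part all 3 pairs of numbers as the real one does, the other 3 gave at most 1 call, while the 6 that part fewer gave up to 146.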
